A study of Nothobranchius furzeri with 15 samples.

How the data were processed

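RNA was measured in 15 liver libraries of male turquoise killifish (Nothobranchius furzeri, a short-lived annual fish) of the GRZ strain, an inbred laboratory strain, at 9 weeks of age. Per the labels, 5 libraries came from the DMSO group (the solvent control), 5 from rotenone at 15 pM and 5 from rotenone at 150 pM. Rotenone is an inhibitor of complex I of the mitochondrial respiratory chain. Libraries are named here by group and by the number in the submitters' sample titles, which runs from 1 to 5 for DMSO and for 15 pM and from 8 to 12 for 150 pM. The labels give no tank, family, extraction day or sequencing batch, so such differences cannot be told apart from the groups. They do not say that each library came from a different fish, and p-values measure only the spread between these samples, which may be partly technical.

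Per the labels' protocols, libraries were made from total RNA with the TruSeq RNA kit v2, which does not mark strand. The submitters' processing notes list CASAVA 1.8.2, STAR 2.4.1d and featureCounts 1.4.6-p4, with no role or order. The genome build, the annotation and the treatment of reads that map to several genes are not given in the sources used here. The authors deposited read counts per gene, which are whole numbers and not normalized, for 26739 gene identifiers. No row lacked a gene identifier. Genes that share reads with a near-identical copy, and overlapping or antisense genes, could not be told apart in these counts, and their values are uncertain.

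The authors also deposited a table named RPKM (reads scaled by gene length and by library total). These RPKM values were checked against the deposited counts over 104835 values with more than 200 counts and an RPKM over 2. Dividing by the library's own total gave 1 gene length within 0.2% for 7.91% of the values. Library totals taken in turn down the gene rows, as when a vector is recycled over a matrix, gave 1 length within the same tolerance for 100% of them. In the whole table, 6.67% of the values had been divided by their own library's total, and the others were off by a factor between 0.622 and 1.61. The deposited RPKM therefore served only as an alternative and to recover gene lengths, which had a median of 2441 bases over the 22244 genes with a count.

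Genes were tested with edgeR 4.0.16 (quasi-likelihood F-test, two-sided) in R 4.3.3 on the deposited counts. All 15 libraries entered 1 fit with 1 mean per group, TMM normalization and no covariate. The filterByExpr function (minimum count 10) kept 15834 genes, which held 99.9% of all counts. It left out 10905 genes, of which 4495 had 0 counts in all libraries. P-values were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison, with a threshold of 0.05. The 3 pairwise comparisons of groups were tested, and a test with 2 degrees of freedom asked whether the 3 groups differed. Fold changes are given on the log2 scale with their standard errors (SE), and expression as CPM (counts scaled to a common library total, with TMM factors), as mean ± SD over the 5 libraries of a group. These choices, and the alternatives for them, were made before the data were examined, except where the text says otherwise.

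The test was tried on simulated data drawn from the real means, library sizes and dispersions, with 200 of the 15834 genes changed. For 15 pM against DMSO it recovered 2.99% of the genes changed 1.5-fold, 26.9% of those changed 2-fold and 78.8% of those changed 4-fold. For 150 pM against DMSO these shares were 0%, 23.9% and 75.8%, and for 150 pM against 15 pM they were 4.48%, 38.8% and 69.7%. Wrong calls numbered 1 of 73, 1 of 67 and 3 of 78 in the 3 simulations. Changes of 2-fold and below were therefore mostly missed in these simulations. The shares depend on how many genes change, since this sets which p-values pass the adjustment. The real comparisons called 667, 896 and 2240 genes, so the shares need not hold there.

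Total counts ranged from 22185038 to 35672589 per library. A count of 0 allows up to 3 counts, or between 0.0841 and 0.135 CPM depending on the library, for counting error only. Within groups, the 30 pairs of libraries differed by 46.7 to 853 times the variance of sampling noise (chi-square per degree of freedom), so no library was counted as a copy of another.

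The file identifiers carry no gene symbols, and none of them was found in the reference table used here (38438 genes of the assembly NfurGRZ-RIMD1). The files do not pair identifiers with names. The 41 gene lists fixed beforehand (respiratory chain, energy metabolism, stress responses and markers of other cell types) could not be applied, and no list was tested. The rule for named genes took, among genes past the threshold with a symbol and a mean of at least 5 CPM, the largest changes of each comparison. It names no gene, because the sources used here give no symbol for these identifiers. In its place, 4 identifiers are printed, the largest rise and the largest fall against DMSO at each dose under the same rule without the symbol, and this choice was made after their values were seen.

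Alternatives were edgeR with RLE size factors, upper-quartile normalization or robust fitting, DESeq2 1.42.0 (Wald test, and a likelihood ratio test for the 3 groups), limma 3.58.1 (voom with and without sample quality weights, and limma on log2 of the deposited RPKM plus 0.1 or 1), 1 surrogate variable from sva 3.50.0, no filter or a filter of 1 CPM in 10 libraries, thresholds of 0.01 and 0.1, a 1.5-fold minimum, the 10 libraries of a comparison alone, the title number as a block, and leaving out each library in turn. Added after seeing the data were fits without 15 pM library 4 and 150 pM libraries 8 and 10, or without the latter pair alone, RPKM recomputed with own totals, a requirement that the groups not overlap, removal of each library's trend with gene length (a lowess curve as an offset), and library totals with no TMM factors in the same edgeR test.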

Results

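Liver RNA was counted in 3 groups of 5 libraries from male killifish of the GRZ strain, which had been given the solvent DMSO, rotenone at 15 pM or rotenone at 150 pM. Total counts per library averaged 28297928 ± 4248726 in DMSO, 27180830 ± 2704866 at 15 pM and 26166193 ± 3053237 at 150 pM (SD, n = 5 each). The 10 most abundant genes of each library took 28.3 ± 1.12% of its counts in DMSO, 29.8 ± 2.22% at 15 pM and 24.7 ± 4.46% at 150 pM (SD, n = 5 each). At 150 pM this share was 21.2% and 19.1% in libraries 8 and 10 and 25.3% to 29.9% in the other 3, and DMSO libraries ranged from 27.0% to 29.8%. Of 15834 genes tested, 2441 (15.4%) differed among the 3 groups (edgeR quasi-likelihood test, adjusted p under 0.05). Without DMSO library 2 the number was 1611, and it was 1293 without 150 pM libraries 8 and 10.

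The first principal component of log2 CPM held 28.8% of the variance and the second 16.1%. The 5 libraries of 150 pM had first-component values between 29.6 and 53.5, above those of all 10 other libraries. Among the 15 pM libraries, library 4 lay at -125.9, and the other 4 lay between -20.5 and 25.9. Its median correlation with its own group was 0.855, whereas the other 14 libraries ranged from 0.936 to 0.972. At 150 pM, libraries 8 and 10 had second-component values of 69.8 and 59.6, and the other 3 lay between -0.80 and 9.34.

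**Figure D1:**
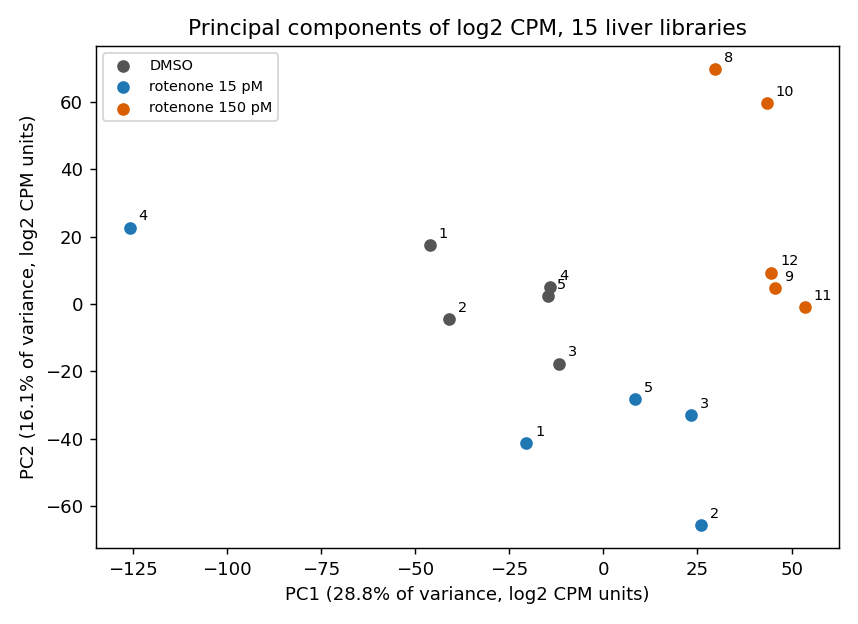
First and second principal components of log2 CPM over 15834 genes (log2 CPM units, share of variance on each axis). Each point is a library, coloured by group and numbered as in the sample titles, and library 4 of 15 pM lies at -125.9 on the first component, apart from the other 14.

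The comparison of 15 pM with DMSO asked which liver transcripts differed at the lower dose. Most of the changed genes were lower with rotenone: 584 genes fell and 83 rose, 667 of 15834 in all. The genes that fell had a median log2 fold change of -1.37, and 404 of them were at least 2-fold lower. Those that rose had a median log2 fold change of 0.80, and 30 of them were at least 2-fold higher. Both numbers moved with single libraries. The rises were 34, 27, 49 and 34 without DMSO library 1, 2, 4 or 5, and 48 and 289 without 15 pM library 1 or 4. The falls were 255, 231 and 284 without DMSO library 1, 2 or 5, then 213, 253 and 321 without 15 pM library 1, 2 or 5, 1084 without 15 pM library 4, and 382 without 150 pM library 12. With library totals in place of TMM in the same edgeR test, 24 of 505 called genes rose (4.75%, against 12.4%) and 481 fell, while RLE factors gave 97 rises of 579 (16.8%) and upper-quartile factors 100 of 640 (15.6%). Among fits that change the test as well, limma on log2 of the deposited RPKM plus 0.1 gave 14 of 546 (2.56%) and DESeq2 405 of 1354 (29.9%). Among called genes with a mean of at least 5 CPM, Nfu_g_1_023228 rose most. It went from 0.488 ± 0.251 CPM in DMSO to 67.7 ± 70.4 CPM at 15 pM (SD, n = 5 each), a log2 fold change of 7.11 (SE 0.81, edgeR adjusted p = 0.000713). All 5 libraries of 15 pM, from 13.5 to 187 CPM, lay above all 10 others, and the 150 pM group was at 0.391 ± 0.245 CPM. Under the same minimum of 5 CPM, Nfu_g_1_012951 fell most, from 20.3 ± 19.5 to 0.608 ± 0.995 CPM (SD, n = 5 each), a log2 fold change of -5.04 (SE 0.997, edgeR adjusted p = 0.0133). In that gene the highest 15 pM library, at 2.37 CPM, lay below the lowest DMSO library, at 4.44 CPM.

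Changed genes at 15 pM were of low and middle abundance. Of the 142 genes above 1000 CPM, which held 58.2% of the counts, edgeR called 0, with 7 at an unadjusted p under 0.05, limma voom 0, limma voom with quality weights 2 and DESeq2 3. Genes between 1 and 10 CPM included 27 that rose and 309 that fell. The genes that fell had a median length of 3551 bases, those that rose 1728 bases, and those not called 2793 bases. After each library's trend with length was removed, 502 genes were called, and these medians were 2762, 3136 and 2810 bases. The removal itself acts on the lengths of the called genes, so this reversal is no evidence about them. In 6.25% of all genes tested the CPM values of the 2 groups did not overlap, against 0.794% by chance for 5 against 5. Of the 667 called genes, 497 were among these. The number of calls depended on single libraries, and it was also lower with the 10 libraries of the comparison alone. It was 289, 258 and 318 without DMSO library 1, 2 or 5, it was 261, 310 and 378 without 15 pM library 1, 2 or 5, 443 without 150 pM library 12, and 1373 without 15 pM library 4.

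The comparison of 150 pM with DMSO asked the same of the higher dose. Here 558 genes fell and 338 rose, 896 in all. The genes that fell had a median log2 fold change of -2.10, and 149 of them were at least 8-fold lower. Genes that rose had a median log2 fold change of 1.07, and 41 of them were at least 8-fold higher. The rises were 163, 64, 139, 162 and 146 without DMSO library 1, 2, 3, 4 or 5, they were 148 and 140 without 150 pM library 8 or 10, and 893 without 15 pM library 4. The falls were 341 and 251 without DMSO library 1 or 2, 367 without 150 pM library 12, and 1049 without 15 pM library 4. DESeq2 gave 928 rises and 931 falls. Among called genes with a mean of at least 5 CPM, Nfu_g_1_019655 fell most. It went from 187 ± 134 CPM in DMSO to 0.956 ± 0.635 CPM at 150 pM (SD, n = 5 each), a log2 fold change of -7.62 (SE 1.47, edgeR adjusted p = 0.0092). Its 5 DMSO libraries, from 32.8 to 386 CPM, all lay above its 5 libraries of 150 pM, from 0.235 to 1.92 CPM. At 15 pM it was at 34.9 ± 50.2 CPM (SD, n = 5), which did not pass the test against DMSO (log2 fold change -2.42, SE 1.14, edgeR adjusted p = 0.274). This call missed the threshold with limma voom (adjusted p = 0.0683) and without 150 pM libraries 8 and 10 (adjusted p = 0.0546).

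Nfu_g_1_006927 had the largest rise at 150 pM by the fit among called genes with a mean of at least 5 CPM. Its log2 fold change was 7.17 (SE 1.60, edgeR adjusted p = 0.0198), and 2 libraries carried this rise. The gene stood at 268 CPM in library 8 and 267 CPM in library 10, and between 0.61 and 0.957 CPM in the other 3. DMSO libraries held 0.74 ± 0.117 CPM (SD, n = 5). Without libraries 8 and 10 the log2 fold change was 0.15 (edgeR adjusted p = 0.855), and adjusted p was 0.457 with limma voom. It was 0.0502 without DMSO library 1 and 0.0668 without DMSO library 2. Libraries 8 and 10 shared 149 genes at least 4-fold above the other 3 libraries of their group, and 48 of the 338 genes that rose against DMSO were among them.

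**Figure D2:**
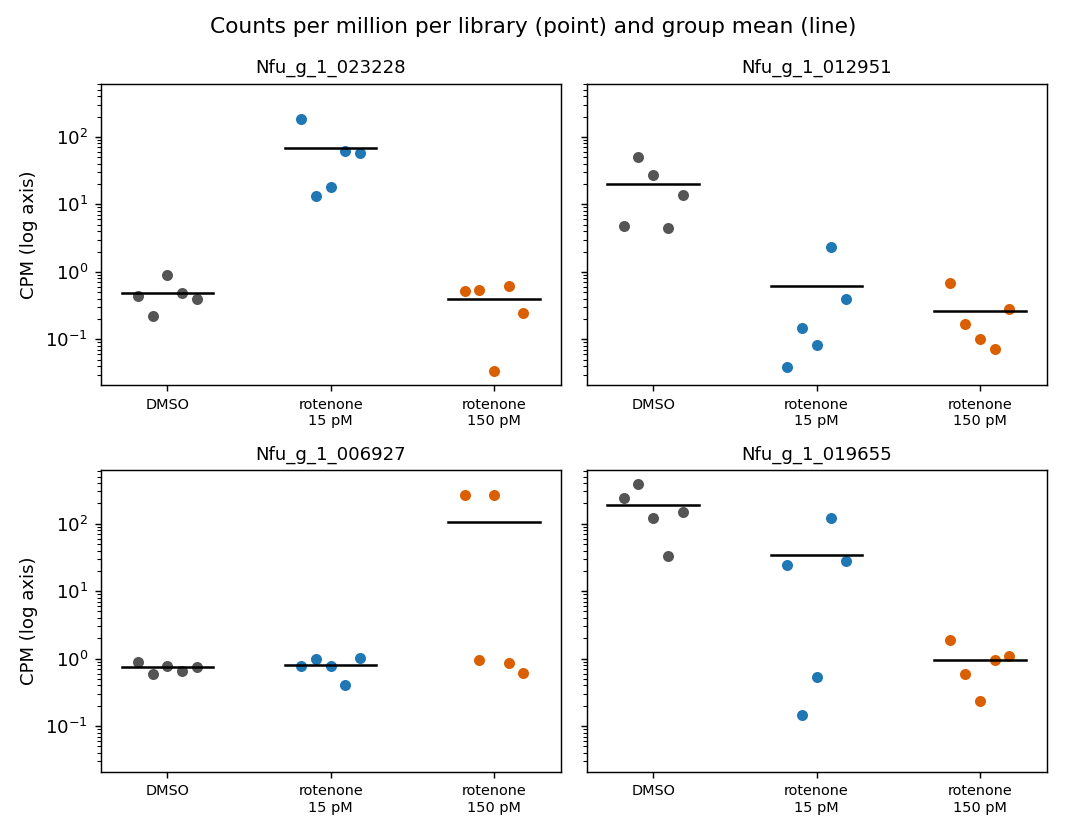
CPM (log axis) of the 4 printed genes in each library (points) and the group mean (line), by group. Nfu_g_1_023228 is above 13 CPM in all 5 libraries of 15 pM and under 1 CPM elsewhere, and Nfu_g_1_006927 is near 267 CPM in 2 libraries of 150 pM.

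At 150 pM, of the 142 genes above 1000 CPM, 1 rose and 3 fell. Genes that rose had a median length of 3717 bases, those that fell 2320 bases and those not called 2817 bases. After each library's trend with length was removed, with 856 genes called, these medians were 2865, 2452 and 2824 bases. The removal itself acts on these lengths. Groups did not overlap in 804 genes that were higher and 982 that were lower, against 0.794% of the genes tested by chance, and in 712 of the 896 called genes. The number of calls was 504, 315, 597 and 555 without DMSO library 1, 2, 3 or 5, it was 529 without 150 pM library 10, and 1942 without 15 pM library 4, which is not in the comparison but is in the shared fit. It was 422, of which 77 rose, without libraries 8 and 10. With library totals in place of TMM in the same edgeR test, 26.8% of 511 calls were higher, against 37.7% of 896. Limma on log2 RPKM plus 0.1, which changes the test, the pseudocount and the scaling together, gave 22% of 601 with each library's own total and 7.88% of 584 with the deposited values, and limma voom with TMM gave 32.4% of 843.

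The 2 doses were compared directly. Between them 2240 genes differed, and 1448 were higher and 792 lower at 150 pM than at 15 pM. That the doses differed in more genes from each other than from DMSO depended on the fit. With the 10 libraries of each comparison alone, more genes were called between 150 pM and DMSO. Without 15 pM library 4 and 150 pM libraries 8 and 10, calls numbered 1496 and 1362 against DMSO at 15 pM and 150 pM, and 1340 between the doses. The lower genes numbered 450 and 525 without 150 pM library 8 or 10, they numbered 350 with library totals in place of TMM, and 1522 with DESeq2. Without both of these libraries 677 genes were higher and 184 lower. The median log2 fold change was 1.11 among the higher genes and -0.73 among the lower ones. Of the 2240 genes, 400 also differed between 15 pM and DMSO, 388 between 150 pM and DMSO, and 1487 in neither. Among these 1487 genes, 860 had a mean below DMSO at 15 pM and above DMSO at 150 pM by the fitted fold changes, and 586 the opposite. Genes called between the doses but against DMSO at neither tend to have DMSO between the doses. This choice of genes therefore nearly sets the tally, which is no evidence of opposite effects. Nfu_g_1_023228 was lower at 150 pM than at 15 pM by a log2 fold change of -7.43 (SE 0.83, edgeR adjusted p = 0.000176), and Nfu_g_1_019655 by -5.19 (SE 1.33, adjusted p = 0.0191). Of the 142 genes above 1000 CPM, 2 were higher and 3 lower.

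The genes higher at 150 pM than at 15 pM had a median length of 4359 bases, the lower ones 2222 bases and those not called 2756 bases. Across 15834 genes, the Spearman correlation of a library's deviation from the gene mean with gene length was 0.10 ± 0.049 at 150 pM and -0.098 ± 0.062 at 15 pM (SD, n = 5 each), a difference of 0.20 (exact permutation test, two-sided, p = 0.0079, the smallest that 5 against 5 can give). Genes are not independent replicates, and the test is over libraries. It was not among the tests fixed beforehand, and it uses the same libraries that gave the calls and their lengths. DMSO libraries were at 0.0026 ± 0.061. After each library's trend with length was removed, 1886 genes were called, of which 1689 were among the 2240. The median length was then 2948 bases in the higher genes, 3128 bases in the lower ones and 2782 bases in those not called, and the removal itself acts on these lengths. Leaving out any single library gave between 1521 and 2400 calls. Without 150 pM libraries 8 and 10 the number was 861, and it was 1340 when 15 pM library 4 was also left out. With library totals in place of TMM in the same edgeR test, 79.6% of 1715 calls were higher, against 64.6% of 2240. Limma on log2 RPKM plus 0.1 gave 82.8% of 1518 with each library's own total and 85.2% of 783 with the deposited values, and limma voom with TMM gave 70.4% of 1852.

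**Figure D3:**
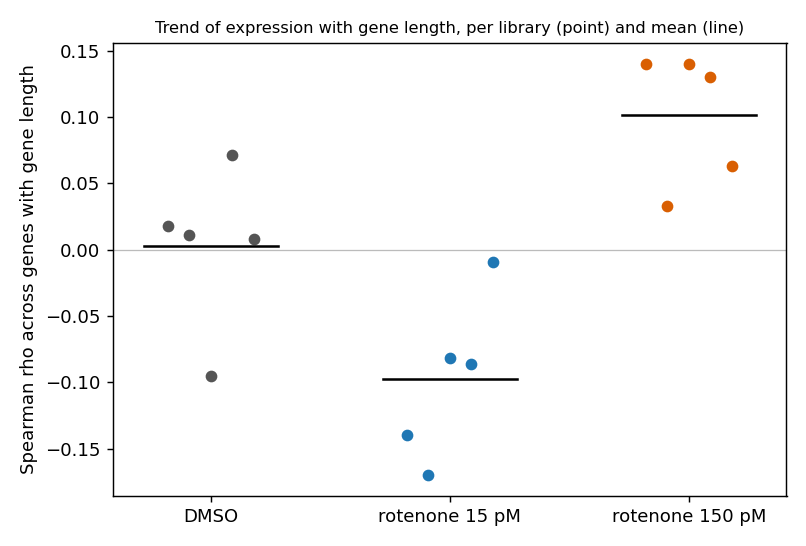
Spearman correlation across genes of each library's log2 CPM deviation from the gene mean with gene length (points), with the group mean (line). The 5 libraries of 150 pM lie between 0.033 and 0.14 and those of 15 pM between -0.17 and -0.0097.

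Pairs of calls placed genes in sets, whose sizes depended on single libraries and on the test. At 15 pM, 348 genes were below both other groups, with a median log2 fold change of -1.12 against DMSO. This number was 149, 164, 213 and 163 without DMSO library 1, 2, 4 or 5, it was 131, 156 and 185 without 15 pM library 1, 2 or 5, and 228 without 150 pM library 12. The 15 pM group was above both others in 43 genes, in 21, 14, 23 and 20 without DMSO library 1, 2, 4 or 5, in 27 and 126 without 15 pM library 1 or 4, and in 28 without 150 pM library 11. At 150 pM, 240 genes were above both other groups, with a median log2 fold change of 1.14 against DMSO. Here the number was 127, 49, 91, 118 and 105 without DMSO library 1, 2, 3, 4 or 5, it was 466 without 15 pM library 4, and 102 and 92 without 150 pM library 8 or 10. Another 148 genes were below both at 150 pM, with a median of -1.51, and there were 91 and 74 without DMSO library 1 or 2 and 65, 94, 92 and 81 without 150 pM library 8, 10, 11 or 12. Both doses were below DMSO in 161 genes, with median log2 fold changes of -2.12 and -2.46. There were 83, 47 and 90 such genes without DMSO library 1, 2 or 5, then 69, 78, 105 and 96 without 15 pM library 1, 2, 3 or 5, 454 without 15 pM library 4, and 102 without 150 pM library 11 or 12. Without 150 pM libraries 8 and 10 together, in the order given, the 5 sets held 196, 20, 42, 46 and 140 genes, without these and 15 pM library 4 they held 383, 72, 234, 92 and 502, and with library totals in place of TMM 298, 15, 104, 76 and 108. DESeq2 gave 526, 215, 591, 352 and 306, and 1 surrogate variable 750, 159, 484, 259 and 471. Limma voom gave 360, 42, 206, 92 and 256, and with quality weights 551, 133, 520, 211 and 517. The filter of 1 CPM in 10 libraries left 274, 35, 132, 92 and 67. Limma on RPKM, deposited or recomputed, gave 159 to 346, 9 to 17, 34 to 134, 17 to 51 and 206 to 234. The first set held 229 genes with no filter and 226 with the length trends removed.

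Smaller sets moved still more. Both doses were above DMSO in 14 genes, with median log2 fold changes of 0.80 and 0.78. There were 4, 1, 6 and 5 such genes without DMSO library 1, 2, 4 or 5, then 7, 55 and 6 without 15 pM library 1, 4 or 5, and 7 and 6 without 150 pM library 8 or 12. Against DMSO, 26 genes fell at 15 pM and rose at 150 pM, with median log2 fold changes of -1.21 and 1.07. This number was 10, 3, 9, 8 and 6 without DMSO library 1, 2, 3, 4 or 5, it was 10, 10, 45, 68 and 13 without 15 pM library 1, 2, 3, 4 or 5, and 11, 15, 7, 12 and 9 without 150 pM library 8, 9, 10, 11 or 12. Without 150 pM libraries 8 and 10 together these sets held 5 and 2 genes, without these and 15 pM library 4 they held 57 and 26, and with library totals in place of TMM 4 and 9. DESeq2 gave 55 and 98, 1 surrogate variable 45 and 93, limma voom 7 and 40, and voom with quality weights 56 and 121. No filter gave 8 and 15, the filter of 1 CPM in 10 libraries 8 and 16, and limma on RPKM 0 to 1 and 3 to 20. The reverse, a rise at 15 pM and a fall at 150 pM, was called in 0 genes by edgeR, with 28 at an unadjusted p under 0.05 in both comparisons, in 0 by limma voom, 4 with quality weights and 5 by DESeq2.

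**Figure D4:**
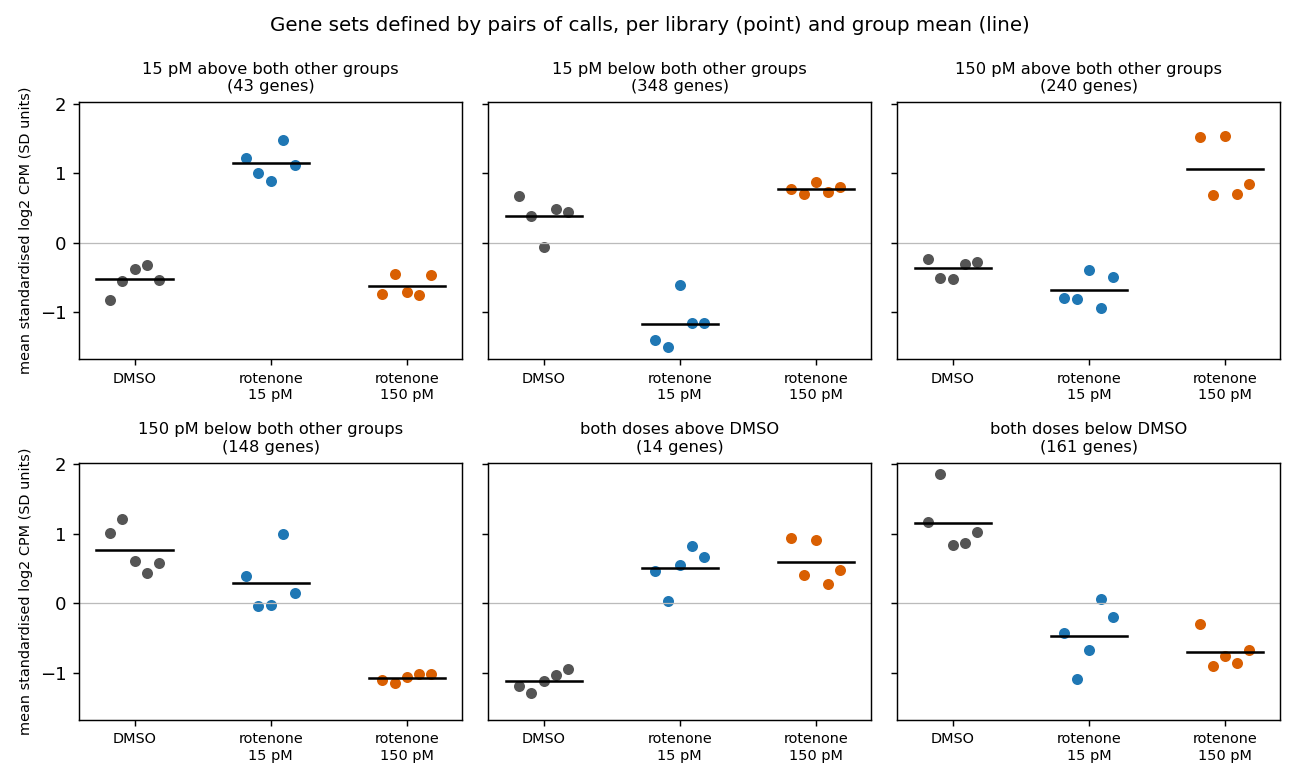
Mean standardised log2 CPM (SD units) of 6 gene sets in each library (points), with the group mean (line). The sets were chosen by calls on the same libraries, and in the 161 genes below DMSO at both doses 15 pM library 4 is at 0.068 while the 5 DMSO libraries lie between 0.842 and 1.86.

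Log2 fold changes of the 2 doses against the same DMSO libraries correlated across 15834 genes with r = 0.37 (jackknife SE 0.18 over libraries). In 40 simulations of unchanged groups, with controls drawn anew and shared by both doses, r averaged 0.499 (range 0.476 to 0.523). Each gene was drawn independently, so the simulations leave out deviations that many genes of a library share. The observed covariance was 0.209 (jackknife SE 0.13) and the simulated one 0.077, a difference of 0.132 that is about the size of its error. With the controls split into sets of 2 and 3, the median r was 0.272 (range 0.0925 to 0.324) and the median covariance 0.161. Here the 2 doses share no control library, so that sharing does not raise r. No simulation gave a value of this measure for unchanged groups. The 161 genes lower at both doses compare with 20.6 for independent lists, and ranged from 47 without DMSO library 2 to 454 without 15 pM library 4. The 14 genes higher at both compare with 1.77, and ranged from 1 to 55 without the same libraries, and 26 genes went opposite ways, with 3 and 68 without them. Simulated unchanged groups shared 0 calls. The simulation leaves out the effects, and the independent lists leave out the shared controls, so neither excess measures a shared effect.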

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

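The tests of wrong labels, of added RNA, of a second RNA source and of single libraries behind the lengths were chosen only after the results were seen, and the removal of length trends, and its test on the lengths themselves, after the lengths of the called genes were seen to differ.

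In 24 groups of 5 values, 5 held a library far from the other 4 by Dixon's ratio. For independent normal values chance gives about 1 in 20. Some groups are CPM of the 4 printed genes, which were chosen for large changes and vary widely, so the excess has no clear reading. DMSO library 1 had 35672589 counts, and the other DMSO libraries had 25160285 to 27649168. Library 1 of 15 pM held 187 CPM of Nfu_g_1_023228, and the others of its group 13.5 to 62 CPM. Library 4 of 15 pM held 2.37 CPM of Nfu_g_1_012951 (0.0383 to 0.402 in the others) and 122 CPM of Nfu_g_1_019655 (0.147 to 27.6 in the others). The median correlation of that library with its own group was 0.855, and 0.951 to 0.96 in the others.

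Library 4 of 15 pM was the first pattern weighed. It held 85 genes at least 4-fold above every other library and 305 at least 4-fold below, where no other library had over 31 and 12. Lower depth was argued against. After all libraries were thinned to the lowest total, its median correlation stayed at 0.855, with 0.95 the lowest of the others of its group. The 305 low genes do not decide on RNA added from other cells. Such RNA lowers genes that are scarce in it, while genes that both sources hold keep their level. A wrong label was argued against only for a library like those of the other groups. In 59.3% of the 733 genes that set the other 4 libraries apart, library 4 also lay beyond all 10 libraries of the other groups. The other 4 libraries of 15 pM, each left out in turn, did so in 57.2% to 91.4% of such genes. A library like those 10 would do so in about 9.1%. Library 4 stands apart from all others, so that share need not hold for it. Placing it by the nearest group mean, tried first, gave 56.3% for 15 pM, within the 40.8% to 91.4% of the others. That did not decide, since library 3 of 15 pM, at 40.8%, lay nearest DMSO in 51.1%. A wrong label of a library unlike those 10 stays open, as does added RNA. A difference of the individual fish or its handling stays open and untested.

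Libraries 8 and 10 of 150 pM were the second pattern, with 149 genes at least 4-fold above the other 3 libraries of their group, where the next pair in any group had 34. These genes took 0.601% and 0.634% of the counts of the 2 libraries and at most 0.0811% elsewhere. Depth was argued against, since 95.3% of the genes remained after thinning. A wrong label was argued against only for a library like those of the other groups. The lower of the 2 libraries lay beyond all 10 other-group libraries in 67.1% of 1064 genes, against 9.1% for such a library. The nearest group mean, tried first with a bound of 50% set beforehand, gave 47.7% and 79.5%, with 46.9% to 56.9% in the other 3. RNA from a second source stays open: the log2 ratio of library 8 to library 10 spread less over these genes than over others of like abundance, with an SD ratio of 0.643, but choosing genes raised in both libraries narrows it, and 1 of 4 other pairs whose genes were chosen alike lay lower (0.596 to 2.14). No marker list could be applied to unnamed identifiers, and a response of these fish to the higher dose stays open and untested.

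The third pattern was the genes called between 150 pM and 15 pM and their lengths. A length trend in each library was argued against as the whole cause of the calls, since 75.4% of the 2240 remained in the same direction after it was removed. Whether it accounts for the lengths cannot be told apart from a dose effect: the removal took the median length of the higher genes from 4359 to 2948 bases and of the lower ones from 2222 to 3128 bases, a difference of -180 bases, but removal sets this outcome and the trends of the 2 groups did not overlap. A single library of either dose, or 150 pM libraries 8 and 10 together, was argued against for the lengths, since the higher genes stayed at least 1849 bases longer by their medians when any of these was left out. Trends shared by a whole group, from RNA quality or a library batch, cannot be separated from the dose by these labels, and a dose effect on long genes is equally open and untested.

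Other groupings of the libraries rarely called genes. For 15 pM against DMSO, 1 of 100 splits, the real one, gave as many genes, with 667 against at most 62 in the others. For 150 pM against DMSO it was also 1 of 100, with 896 against at most 19, and between the doses 1 of 100, with 2240 against at most 64. For the 3 groups it was 1 of 100, with 2441 against at most 7. Chance assignment of libraries is thereby made unlikely for these counts, if the libraries are independent, which the labels do not say. A share of 1 of 100 is the smallest that 100 splits can give. A batch that follows the groups is not addressed by this test.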

How the results depend on the processing

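The settings that leave out chosen libraries, recompute RPKM, require no overlap, remove length trends or replace TMM by library totals were added after the data were seen. No printed gene changed direction under any setting run, and the cause of the shifts below was not tested unless given. The surrogate variable was 0.874 in 15 pM library 4 and between -0.236 and 0.174 in all other libraries. Its fit and those without library 4 are therefore not separate checks. RLE, upper-quartile and robust edgeR, limma voom, no filter, the 1.5-fold minimum and removed length trends kept all 4 counts of genes within 1.5 times.

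For 15 pM against DMSO (667 genes) the number was 1354 with DESeq2 (29.9% higher, against 12.4%), 1627 with quality weights, 1836 with 1 surrogate variable, 1496 without 15 pM library 4 and 150 pM libraries 8 and 10, 276 with the 10 libraries alone, 146 and 1163 at thresholds of 0.01 and 0.1, and 258 to 1373 with a library left out. For 150 pM against DMSO (896) it was 1859 with DESeq2 (49.9% higher, against 37.7%), 2076 with quality weights, 1707 with 1 surrogate variable, 453 with the filter of 1 CPM in 10 libraries, 584 and 531 with the deposited RPKM plus 0.1 and 1, 511 with library totals in place of TMM, 422 without libraries 8 and 10, 1362 without these and 15 pM library 4, 1812 with the 10 libraries alone, 214 and 1673 at the 2 thresholds, and 315 to 1942 with a library left out. Between the doses (2240) it was 783 and 675 with the deposited RPKM, 1389 with recomputed RPKM plus 1, 861 without libraries 8 and 10, 1340 without all 3 libraries, 1043 with the 10 libraries alone, 756 and 3572 at the 2 thresholds, 1427 with no overlap of the groups, and 1521 to 2400 with a library left out; DESeq2 gave 3314 (54.1% higher, against 64.6%). Among the 3 groups (2441) it was 3841 with DESeq2, 3875 with quality weights, 3878 with 1 surrogate variable, 1222 and 1049 with the deposited RPKM, 1293 without libraries 8 and 10, 864 and 3676 at the 2 thresholds, and 1611 to 3521 with a library left out. Fewer samples, or the threshold itself, set part of these changes by construction. The correlation of the 2 doses' fold changes (0.37) was 0.612 without the 3 libraries, and 0.313 to 0.513 with a library left out.

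Title numbers 1 to 5 follow the letters GC for DMSO and GR for 15 pM, and no label says that equal numbers mark a pair. The numbers did not pair the libraries: same-numbered deviations correlated between -0.0525 and 0.0914, 0 of 5 over 0.1, and 0 of 5 correlated best with their own number. With the number as a replicate block, 1 gene, which was higher, was called in the 10 libraries, against 276 without the block. The block takes degrees of freedom from this fit, which can lower the number of calls by itself. The adjusted p of Nfu_g_1_023228 and Nfu_g_1_012951 was then 0.142 and 0.181. The gene list tests and their alternatives, and the rest of the rule for named genes, were not run, because the identifiers carry no names. Depth was similar across groups. The spread between libraries was a biological coefficient of variation of 38.4%. How far it limited detection below 2-fold was not tested, since the simulations did not vary it and changed only 200 genes.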

Other observations

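The comparisons of adjacent rows were chosen after the data were seen. The deposited files give no coordinates, so neighbours here are adjacent rows among the genes tested. Nearby rows often hold nearby identifier numbers but not in number order, so adjacent rows need not be adjacent genes. Genes below DMSO at 150 pM stood beside each other in 65 pairs, against a mean of 19.5 and a maximum of 37 over 1000 random draws of as many genes. Genes above DMSO at 15 pM formed 6 such pairs, against a mean of 0.423 and a maximum of 4, and genes higher at 150 pM than at 15 pM formed 184, against 132 and 169. For genes below DMSO at 15 pM, above DMSO at 150 pM, and lower at 150 pM than at 15 pM, the pairs numbered 35, 16 and 57, reached in 7, 2 and 2 of the 1000 draws. The draws took genes singly from all those tested, without regard to abundance or joint expression. Near-identical copies or overlapping genes that share reads may also stand in adjacent rows. What lies behind these excesses was not tested.

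Within 9 rows of the table, which hold 7 tested genes, 5 genes rose at 15 pM by log2 fold changes between 3.78 and 6.62. In all 5 genes each of the 5 libraries of 15 pM, library 4 included, lay above all 10 libraries of DMSO and 150 pM. Random draws of as many genes, with the same limits as above, placed at most 3 within 10 rows. Nfu_g_1_023228 is not among these genes.

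DMSO library 1, the most deeply counted, held 76 genes at least 4-fold above the other DMSO libraries, and the other 4 held 3 to 14.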
